A study of Mus musculus with 6 samples.

How the data were processed

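Total RNA from mouse colon tumours was hybridised to 6 Affymetrix expression arrays, 1 sample per array. The design text counts 3 control mice and 3 mice carrying a human IL8 transgene, all on a mixed CBA/C57BL/6 background. IL8 (CXCL8) is a human chemokine that attracts neutrophils, and mice have no direct counterpart of the gene. The labels record total RNA extraction with Trizol, biotin labelling and, for every animal, male sex. Samples were grouped by title and genotype, since the source label of the transgenic samples also contains the word control. How the tumours arose is not given in the sources used here. Neither the design text nor the labels say whether an array holds 1 tumour or several, so p-values measure only the spread between these samples, which includes any difference in how they were dissected.

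The deposited values are log2 expression values made by the authors with GCRMA, a method that corrects probe intensities for background and summarises them per probe set, per the submitters' processing notes. The GCRMA version and the genome build are not given in the sources used here. The log2 scale was read from the range of the values, and the arrays had medians of 3.31 to 3.36. The values were used as deposited, with no further normalization. A probe set is a group of short probes that read 1 transcript, and several probe sets can stand for a gene. Gene names came from the platform annotation table supplied with the values. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had no gene listed, which leaves them unnamed here. Entrez identifiers of 34754 of the probe sets with 1 symbol were found in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was used for names and for placing genes on the X or Y chromosome. No coordinates are given, because the values name no build. No probe set was annotated to the human transgene, so its level was not analysed here.

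A probe set was tested where its log2 value was at least 4 on at least 3 of the 6 arrays, and the 64 AFFX control probe sets were left out. This kept 19310 probe sets, of which 16868 had 1 gene symbol, 511 had several and 1931 had none, and they stood for 10289 genes. Between 41.7% and 43.0% of all probe sets reached 4 on an array. The number of arrays, 3 per group, limits the precision. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, transgenic minus control), with Benjamini-Hochberg adjustment over all probe sets tested. Differences are on the log2 scale and are given with the standard error (SE) of the fit, group levels with the standard deviation (SD). Where a probe set lay under 4 on every array of a group, the fold is a lower bound. It was made by setting that group's arrays to 4 and is written "at least".

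Gene lists were tested with limma's camera function, which asks whether the genes of a list rank higher or lower than the other genes. It used a preset correlation of 0.01 between the genes of a list, 1 probe set per gene (the brightest over all arrays) and Benjamini-Hochberg adjustment over the lists tested. The same test was run with the correlation estimated from the data for each list. Lists with fewer than 5 measured genes were not tested. Of 32 lists, 25 were tested. The lists, the grouping, the tests, the filter, the named-gene rule and all alternatives but 2 were chosen before the data were examined.

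Genes were named by this rule. The first part took up to 12 genes per direction with an adjusted p under 0.05, at least 2-fold difference and non-overlapping groups. Places left over were filled with 1-symbol probe sets of at least 2-fold difference and non-overlapping groups that had the smallest unadjusted p, and these are described as not having passed. The second part took all measured CXCR2 ligands and receptors together with S100a8, S100a9, Ly6g, Itgam, Ly6c1, Arg1, Nos2, Ptgs2, Il1b, Il6 and Mmp9. The third took up to 4 members with the smallest unadjusted p from each list that passed and from the neutrophil, immature myeloid, macrophage, Wnt, proliferation, colonocyte and goblet cell lists. Ccl7, genes of lists too small to test, and genes used to weigh explanations, are named outside this rule and were chosen after values had been seen.

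The alternatives were no filter, a stricter filter at 6, quantile normalization, centring each array on its median, a trended and robust prior variance, array quality weights, the replicate number as a block, values under 4 set to 4, an adjusted p threshold of 0.1, other forms of the list test and leaving out each array in turn. Alternatives added after seeing the data left out probe sets of named X- and Y-linked genes, alone or together with every probe set under 4 on all arrays of a group. The latter of these selects on the outcome, since it removes probe sets that were switched off in a group.

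The procedure was tested on simulated data for this comparison, with 19310 probe sets and 3 arrays per group. Of 50 probe sets changed by 1 on the log2 scale it called 8, of 50 changed by 2 it called 42, of 50 changed by 4 it called 50 and of 50 changed by 8 it called 49. It also called 7 unchanged probe sets. It called 3 of 3 shifted lists and 0 of the unchanged lists. The simulated noise was drawn independently for each probe set, with the same spread in both groups. In the data the estimated correlation within a list reached 0.870. The simulation therefore cannot show how the list test behaves where the genes of a list vary together.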

Results

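Gene expression was measured on 6 arrays, 3 from colon tumours of control mice and 3 from colon tumours of mice carrying a human IL8 transgene. The comparison asks how the transgene goes with gene expression in the tumour. Within the control group, pairs of arrays correlated at 0.975 to 0.983 across probe sets, and within the transgenic group at 0.925 to 0.954. The highest correlation between groups was 0.987, above every pair within a group. The median within-group SD was 0.200 on the log2 scale in control and 0.315 in transgenic tumours. Genes are not independent replicates, so these correlations only describe the arrays.

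Of the 11 probe sets that passed, 6 belong to named genes of the sex chromosomes. Xist, the RNA that coats the inactive X chromosome, rose from 2.47 ± 0.16 to 12.65 ± 0.33 (SD, n = 3 per group), at least 400.5-fold. The Y-linked genes Eif2s3y, Kdm5d and Uty all fell to background. Eif2s3y, a translation initiation factor subunit, went from 10.09 ± 0.12 to 2.53 ± 0.16, at least 68.1-fold lower. Kdm5d, a histone demethylase, went from 7.55 ± 0.12 to 1.81 ± 0.15, at least 11.7-fold lower, and Uty, a relative of the demethylase Kdm6a, from 5.76 ± 0.25 to 2.08 ± 0.43, at least 3.38-fold lower. Ighm, the heavy chain of immunoglobulin M, was the 1 named autosomal gene that passed and rose from 3.99 ± 0.54 to 10.44 ± 1.05. Its control arrays were at 3.36, 4.25 and 4.35, near the level of 4 used as the filter, so that no fold is given. The Ighm call was lost when the named X- and Y-linked genes were left out of the adjustment.

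In all, 11 of 19310 probe sets had an adjusted p under 0.05 with limma, 4 higher and 7 lower in the transgenic tumours. They were 3 probe sets of Xist, 1 of Ighm, 1 each of Eif2s3y, Kdm5d and Uty, and 4 unnamed probe sets that lay under 4 on every transgenic array. The limma adjusted p was 2.54e-05 for Xist and for Eif2s3y, 6.18e-05 for Kdm5d, 0.0117 for Uty and 0.0316 for Ighm. The labels record all 6 animals as male, while all 3 transgenic arrays had Xist at 12.26 or more and all 3 control arrays had it at 2.64 or less. This split coincides with genotype on all 6 arrays, so every difference reported here is also a difference between arrays with and without Xist. Without the named X- and Y-linked genes, 3 probe sets passed, all lower and unnamed. The 4 unnamed probe sets had control means of 6.67 to 9.10 and lay under 4 on every transgenic array. Eif2s3y, Kdm5d and Uty had the same on and off pattern. As the unnamed probe sets have no gene or chromosome here, they are not shown to be separate from sex.

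**Figure D1:**
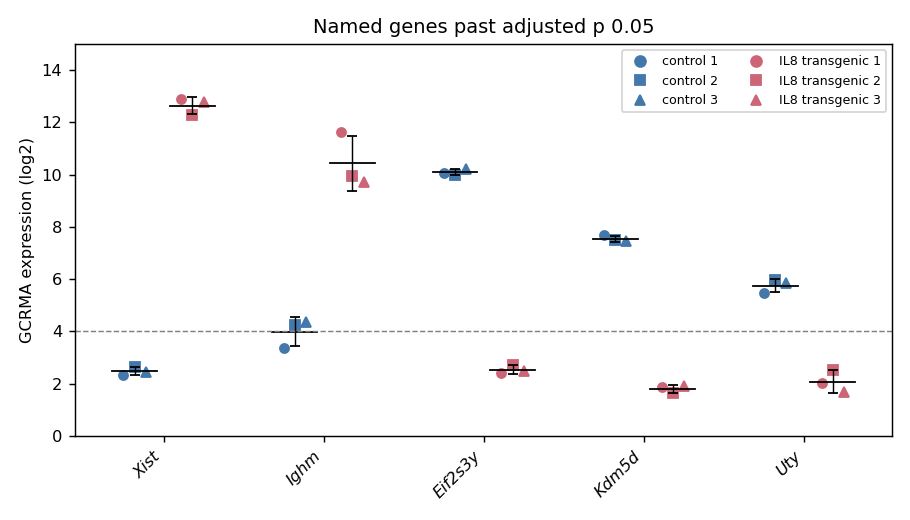
Expression (GCRMA, log2) of the 5 named genes with an adjusted p under 0.05, 1 point per array, control in blue and IL8 transgenic in red, with the mean and SD of 3 arrays in black. The dashed line marks the level of 4. Xist lay at 12.26 or more on the transgenic arrays, and Eif2s3y, Kdm5d and Uty lay under 4 there.

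The Ighm difference was 6.45 ± 0.56 (SE) from the values as deposited and 6.23 with values under 4 set to 4, and its size is uncertain because the control arrays lay near that level. It ran from 5.84 to 6.80 with 1 array left out, but its call was lost in several settings. The limma adjusted p was 0.223 without control array 1, 0.230 without control array 2, 0.274 without control array 3, 0.0949 without transgenic array 2 and 0.0783 without transgenic array 3. It was 0.0897 with no filter and 0.0679 without the named X- and Y-linked genes. It was 0.339 when probe sets under 4 on every array of a group were left out as well. The latter setting selects on the outcome. The Ighm difference stayed at 6.45 in these settings without probe sets of smaller p. Its call thus depended on those probe sets being in the adjustment. Over all alternatives the adjusted p of Ighm ran from 0.00862 to 0.424. All 7 kept Ighm probe sets were higher in transgenic tumours, by 0.89 to 6.45, and the other 6 did not pass. Of these 6, 4 were at 9.79 or more on transgenic array 1 and at 6.71 or less on every other array, and the other 2 were highest on transgenic array 3, at 7.58 and 10.06. The Uty call was lost with quantile normalization (limma adjusted p 0.154), with values under 4 set to 4 (0.0593), without control array 1 (0.0747), 2 (0.124) or 3 (0.153) and without transgenic array 1 (0.0866), in a range of 0.00343 to 0.154 over all alternatives.

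Counting the 11 that passed, 89 probe sets had an unadjusted p under 0.01 and at least 2-fold difference, 38 higher and 51 lower. Without the named X- and Y-linked genes this count was 79, with 33 higher and 46 lower. An unadjusted p under 0.01 alone was reached by 159 probe sets, against 193 that chance would give, and an unadjusted p under 0.05 by 1063 against 965.5. Groups did not overlap for 2109 probe sets, 10.9% of those tested, where chance gives 10%. The count of 89 was 147 without control array 1 (71 higher and 76 lower), 48 without control array 2 (24 and 24), 47 without control array 3 (18 and 29) and 421 without transgenic array 3 (150 and 271). Without transgenic array 1 it was 133, and the balance turned to 86 higher and 47 lower.

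Among the genes that filled the named places without passing, Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 8.41 ± 0.54 in transgenic and 6.50 ± 0.11 in control tumours, a difference of 1.91. Sgk1, a kinase that regulates sodium transport, differed by 1.49, the magnesium channel gene Trpm6 by 1.73 and the translation factor gene Eif2s3x, the X-linked partner of Eif2s3y, by 1.08. Wfdc21 (1.32), Samd4 (1.06), Mctp2 (1.53), 1500009L16Rik (1.20) and Gprin3 (1.15) were also higher, and Lrrc8e was at least 3.27-fold higher. On the lower side, Lect2, a secreted protein, was at 4.82 ± 1.62 in transgenic and 8.76 ± 0.73 in control tumours, a difference of -3.93. The chemokine receptor gene Cx3cr1 differed by -2.48, the lymphocyte receptor gene Cd244a by -1.95, Upk3a by -1.93 and the endothelial transcription factor gene Sox18 by -1.92. Rsrp1 differed by -1.53, and by -0.12 at another of its 3 kept probe sets. The collagen gene Col18a1 differed by -1.47, and Enpep and Prickle1 each by -1.05. Some of these genes lay under 4 on part of the arrays of a group, and with values under 4 set to 4 the difference was 1.48 for Trpm6, 1.20 for Wfdc21, 1.00 for Gprin3, -3.64 for Lect2, -2.31 for Cx3cr1, -1.62 for Cd244a and -1.64 for Upk3a. None of these 19 genes passed with limma, at adjusted p from 0.493 to 0.806.

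Neutrophil genes and the chemokines that act on CXCR2, the receptor that human IL8 binds in mouse neutrophils, went both ways. S100a8 and S100a9, which encode the subunits of calprotectin, were at 11.47 ± 0.30 and 11.35 ± 0.48 in transgenic tumours against 10.68 ± 0.28 and 10.33 ± 0.39 in control tumours, and all 3 transgenic arrays lay above all 3 control arrays for both. The difference was 0.78 ± 0.23 (SE) for S100a8 and 1.02 ± 0.31 for S100a9, and neither passed (limma adjusted p 0.806 for both). Ltf, a neutrophil granule protein, differed by 2.09, and by 0.99 without transgenic array 2, where it was at 10.27, and the gelatinase gene Mmp9 by -1.95 with transgenic array 2 at 4.08 and the others at 6.96 or more, and by -0.83 without that array. Of the mouse CXCR2 ligands, Cxcl5 was at 10.79 ± 0.08 in transgenic and 11.33 ± 0.04 in control tumours, Cxcl3 differed by 0.69 (0.39 without control array 2), Cxcl1 by -0.63, Cxcl2 by 0.17 and Ppbp by 1.24. Cxcl1 differed by -0.017 without transgenic array 2, -1.08 without transgenic array 1 and -0.28 without control array 3, and Cxcl2 ran from -0.42 without transgenic array 1 to 0.60 without transgenic array 2. Ppbp was at 9.90 on transgenic array 2 and at 5.46 or less on the other arrays, and differed by -0.49 without array 2, the array with high squamous epithelium genes (Krtdap at 12.31).

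The neutrophil list, with 8 of 12 measured members higher, did not pass camera (median 0.28, adjusted p 0.102, and adjusted p = 0.580 with an estimated correlation). Its median was -0.19 without transgenic array 1, and the list passed without transgenic array 2, with a median of 0.67. The list of CXCR2 ligands and receptors had a median of 0.17 and a mean of 0.18, while camera ranked it lower (adjusted p 0.905). In that list 0 members passed over all genes and 1, Cxcl5, when adjusted over the list alone. In the neutrophil list 0 passed in either way. Probe sets for Cxcl15, Cxcr2, Ackr1, Itgam, Nos2 and Il6 did not pass the filter. Their highest values on any array were 2.97, 3.09, 5.93, 4.175, 2.58 and 5.01, in that order. Cxcr2 thus stayed under 4 on every array. The annotation table listed no probe set for Cxcr1, Ly6g or Ly6c1, which were not analysed here.

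**Figure D2:**
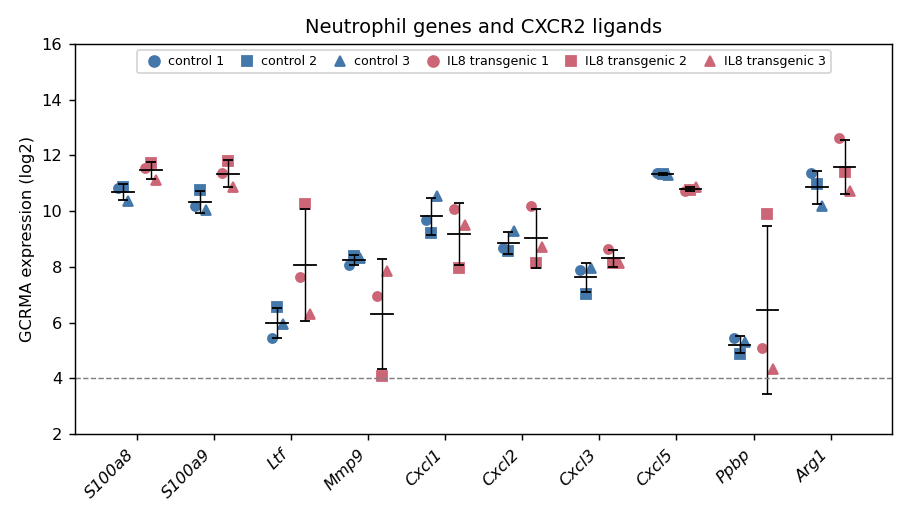
Expression (GCRMA, log2) of neutrophil genes, CXCR2 ligands and Arg1, 1 point per array, control in blue and IL8 transgenic in red, with the mean and SD of 3 arrays in black and the level of 4 dashed. S100a8 and S100a9 lay higher on all 3 transgenic arrays without passing the adjusted test, and Ppbp was at 9.90 on transgenic array 2.

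Immature myeloid and suppressor genes also went both ways, and the list did not pass camera (median -0.18, 8 of 13 members lower, adjusted p 0.538). Its median was -0.34 without transgenic array 1 and -0.10 without transgenic array 2. Arg1, the arginase of suppressive myeloid cells, was at 11.58 ± 0.97 in transgenic and 10.85 ± 0.61 in control tumours, a difference of 0.73 that was 0.21 without transgenic array 1, at 12.63, 0.40 without control array 3 and 1.16 without transgenic array 3. Ncf4, a subunit of the phagocyte oxidase, differed by -1.12. Among inflammatory mediators, Il1b differed by -0.33 ± 0.62 (SE) and Ptgs2, the inducible cyclooxygenase, by -0.25 ± 0.85, and with 1 array left out they ran from -0.98 to 0.26 and from -0.99 to 0.50. The chemokine gene Ccl7, named after its value was seen, had the smallest p of that list and differed by -1.22 ± 0.34 (limma adjusted p 0.806). The list of inflammatory cytokines and mediators did not pass (median -0.31, adjusted p 0.357). In both lists 0 members passed over all genes and 0 when adjusted over the list alone.

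Macrophage and antigen-presentation lists ranked lower in the transgenic tumours with the preset correlation. The monocyte and macrophage list ranked lower in camera (median -1.03, adjusted p 1.89e-06), with 14 of 16 members lower. The call was lost with the correlation estimated (adjusted p = 0.493 with an estimated correlation). Aif1 differed by -2.20, the receptor gene Csf1r by -1.02, the mannose receptor gene Mrc1 by -0.55 and Cx3cr1 by -2.48. In this list 0 members passed over all genes and 1, Cx3cr1, when adjusted over the list alone. The list's mean deviation from the control mean was -1.70 on transgenic array 2, -0.84 on array 1 and -0.46 on array 3, and without array 2 the median was -0.60 and Csf1r differed by -0.62. Array 2 was also the array on which the squamous epithelium gene Krtdap was at 12.31 against 2.62 or less elsewhere.

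The list of dendritic cell and MHC class II genes, which serve antigen presentation, also ranked lower in camera (median -1.53, adjusted p 3.20e-05, and adjusted p = 0.493 with an estimated correlation). All 6 measured members were lower, among them H2-Aa (-1.42), H2-Ab1 (-1.68), the invariant chain gene Cd74 (-1.65) and the integrin gene Itgax (at least 1.36-fold). In this list 0 members passed over all genes, and all 6 passed when adjusted over the list alone. The estimated correlation within this list was 0.870, so the 6 members vary together and are not independent results. Its mean deviation was -2.52 on transgenic array 1, -1.54 on array 2 and -0.57 on array 3, against -0.48 on control array 1, and without transgenic array 1 H2-Aa differed by -0.86 and H2-Ab1 by -1.05. Transgenic array 1 also had the lowest 3′ to 5′ difference of the Gapdh control probe sets, 0.71 against 0.87 to 0.96 on the other arrays. A low difference is not by itself a sign of poor RNA, and its bearing on this or later lists was not tested.

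Wnt and stem cell genes ranked lower (median -0.84, camera adjusted p 0.000372, and adjusted p = 0.640 with an estimated correlation), with 19 of 21 members lower. The Wnt inhibitor gene Apcdd1 differed by -1.66, the ephrin receptor gene Ephb3 by -0.80, Msi1 by -0.92 and Smoc2 by -0.55. This list lay at -2.57 on transgenic array 2 and at -0.23 and -0.21 on the others, and without array 2 its median was -0.16 and these 4 genes differed by -1.08, -0.46, -0.42 and -0.36. With values under 4 set to 4, Msi1 differed by -0.41. On array 2 Krtdap was at 12.31 and Trp63, another squamous epithelium gene, was at 8.97. Fibroblast and collagen genes ranked lower too (median -0.47, 15 of 18 lower, adjusted p 0.000788, and adjusted p = 0.493 with an estimated correlation). Pdgfra, a growth factor receptor of fibroblasts, differed by -1.24, Sparc by -0.59, Col6a1 by -0.88 and the matrix gene Tnc by 0.56. The fibroblast median was -0.28 without transgenic array 1, where Col6a1 differed by -0.55 (that array lay at -0.93 and had the lowest Gapdh 3′ to 5′ difference, 0.71), and -0.73 without array 2, and Tnc differed by 0.33 without control array 2. In both lists 0 members passed over all genes and 0 when adjusted over the list alone.

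Proliferation genes were lower in all 23 measured members (median -0.27, camera adjusted p 0.00526, and adjusted p = 0.646 with an estimated correlation). Pcna, the replication clamp, differed by -0.32, the topoisomerase gene Top2a by -0.37 and the mitotic kinase genes Plk1 and Aurka by -0.64 and -0.73. The list lay at -0.88 on transgenic array 1 and at -0.01 and 0.04 on the other transgenic arrays, so that without array 1 the median was 0.04 and the call was lost. Without that array Top2a differed by -0.22, Plk1 by -0.25 and Aurka by -0.082, and without transgenic array 3 Aurka differed by -1.20. On transgenic array 1 the difference between 3′ and 5′ control probe sets was 0.71 for Gapdh and 1.46 for Actb, against 0.87 to 0.96 and 1.66 to 1.82 on the other arrays. The call was also lost without control array 3 (median -0.21) and with array quality weights (median -0.07), and the median was -0.44 without transgenic array 2. In this list 0 members passed over all genes and 0 when adjusted over the list alone.

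Genes of differentiated colon epithelium ranked higher as lists, and each call was lost without at least 1 of the arrays. Absorptive colonocyte genes had a median of 0.38 with 17 of 20 members higher (camera adjusted p 0.00515, and adjusted p = 0.640 with an estimated correlation), among them the sulfotransferase gene Sult1a1 (2.34), the transporter genes Slc5a8 (2.03) and Slc20a1 (0.46) and Ppargc1a (0.41). Goblet cell genes had a median of 0.62 with all 15 higher (adjusted p 0.00589, and adjusted p = 0.646 with an estimated correlation), among them Galnt12 (0.82), Sytl2 (0.68), St6galnac6 (0.71) and Creb3l1 (0.93). Enteroendocrine genes had a median of 1.55 with all 6 higher (adjusted p 0.00853, and adjusted p = 0.580 with an estimated correlation), among them the hormone genes Gcg (2.18), Insl5 (2.50) and Pyy (1.64) and the granule gene Chga (1.20). Epithelial identity genes had a median of 0.21 with 14 of 15 higher (adjusted p 0.00550, and adjusted p = 0.580 with an estimated correlation), among them Ocln (0.36), Cdx1 (0.92), Cdh1 (0.24) and Klf5 (0.27). In these lists 0 members passed over all genes and 0 when adjusted over the list alone.

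Colonocyte genes were at 1.42 on transgenic array 3, 0.76 on array 2 and -0.57 on array 1, and at 1.02 on control array 1. The colonocyte call was lost without control array 3 (median 0.31) or transgenic array 3 (0.21), and the median was 0.63 without control array 1 and 0.70 without transgenic array 1. Slc5a8 differed by 1.31 without transgenic array 2 and by 1.35 without control array 3, and Slc20a1 by 0.77 without transgenic array 1 and 0.22 without array 3. Goblet cell genes were at 1.49 and 1.29 on transgenic arrays 2 and 3 but at -1.17 on array 1, the lowest of the 6 arrays, and at 0.76 on control array 1. Enteroendocrine genes were at 3.38 and 2.52 on transgenic arrays 2 and 3 but at -0.91 on array 1, below every control array. Transgenic array 1 had the lowest Gapdh 3′ to 5′ difference, 0.71, and transgenic array 2 had Krtdap at 12.31. The goblet cell call was lost without control array 2 (0.29) or 3 (0.43) and without transgenic array 2 (0.20) or 3 (0.24), and the median was 0.99 without control array 1 and 1.35 without transgenic array 1. Creb3l1 differed by 1.78 without transgenic array 1 and 0.27 without array 2, St6galnac6 by 0.37 without array 2, by 1.09 without control array 1 and by 0.43 without control array 3, and Sytl2 by 0.45 without control array 2. The enteroendocrine call was lost without control array 3 (1.14) and without transgenic array 2 (0.60) or 3 (1.25), and the median was 3.04 without transgenic array 1. Gcg, Insl5, Pyy and Chga differed by 1.17, 1.49, 0.54 and 0.66 without transgenic array 2 and by 3.75, 4.63, 3.11 and 1.94 without transgenic array 1. Insl5 also differed by 1.61 without control array 3 and 1.38 without transgenic array 3, and Pyy by 0.90 without control array 3. Gcg was at 2.40 and 2.41 on control arrays 2 and 3 and at 2.26 on transgenic array 1, under the level of 4, and differed by 1.69 with values under 4 set to 4. Insl5 was at 2.33 on control array 3 and 2.35 on transgenic array 1. The epithelial identity call was lost without control array 3 (0.09), and the median was 0.13 without control array 2 and 0.12 without transgenic array 2, where Cdx1 differed by 0.43 and Klf5 by 0.15.

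Smooth muscle genes ranked higher (median 0.89, 8 of 10 higher, camera adjusted p 0.0165, and adjusted p = 0.646 with an estimated correlation), among them the contractile protein genes Cnn1 (3.01), Synm (2.18), Synpo2 (2.11) and Actg2 (1.52). They lay at 2.65 and 1.57 on transgenic arrays 2 and 3 and at -1.03 on array 1. Array 2 also had the squamous epithelium genes Krtdap at 12.31 and Trp63 at 8.97. Cnn1 lay under 4 on control arrays 2 and 3 and transgenic array 1, and Synpo2 on control array 3 and transgenic array 1, and with values under 4 set to 4 they differed by 2.89 and 2.27. The call was lost without transgenic array 2 (median 0.14) or 3 (0.76), without control array 3 (0.65) and with the stricter filter (0.15), and the median was 1.85 without transgenic array 1. Cnn1, Synm, Synpo2 and Actg2 differed by 1.82, 1.20, 0.81 and 0.61 without transgenic array 2 and by 4.92, 3.52, 3.64 and 2.94 without transgenic array 1. In this list 0 members passed over all genes and 0 when adjusted over the list alone.

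Circadian clock, hypoxia and immediate early genes ranked higher with the preset correlation. Circadian clock genes had a median of 0.37 with all 11 higher (camera adjusted p 7.02e-05, and adjusted p = 0.493 with an estimated correlation), among them Per1 (1.11), Tef (0.64), Cry1 (0.41) and Arntl (0.37), and the call was kept without each array in turn, while Tef differed by 0.42 without transgenic array 2. Hypoxia and glycolysis genes had a median of 0.31 with 12 of 15 higher (adjusted p 0.000440, and adjusted p = 0.493 with an estimated correlation), among them the carbonic anhydrase gene Car9 (1.21), Pdk1 (0.79), Ankrd37 (0.59) and Vegfa (0.60). Their median was 0.53 without control array 1 and 0.20 without transgenic array 1, where Vegfa differed by 0.36. Immediate early genes had a median of 0.38 with 11 of 12 higher (adjusted p 0.00175, and adjusted p = 0.580 with an estimated correlation), among them Fos (0.69), Nr4a1 (0.99), Dusp1 (0.74) and Klf6 (0.68). They lay at 0.96 on transgenic array 1, which had the lowest 3′ to 5′ differences of Gapdh and Actb, and at 0.11 and 0.14 on the others, and the call was lost without array 1 (median 0.14), while the median was 0.64 without array 3. Nr4a1 differed by 0.50 and Dusp1 by 0.31 without transgenic array 1, and Fos by 0.39 and Klf6 by 0.38 without control array 3. In these lists 0 members passed over all genes and 0 when adjusted over the list alone.

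The B and plasma cell list ranked higher (median 0.25, mean 1.54, all 5 higher, camera adjusted p 0.00515, and adjusted p = 0.493 with an estimated correlation), and Ighm was the 1 member that passed, both over all genes and when adjusted over the list alone. Blnk differed by 0.25, Mzb1 by 0.67 and Jchain, the joining chain of secreted immunoglobulin, by 0.25. The call was lost without control array 3 (median 0.10), without transgenic array 1 (0.24) or 3 (0.20) and with no filter (0.01), and the median was 0.54 without control array 1 and 0.40 without transgenic array 2. Mzb1 differed by 0.10 without control array 3 and by 0.20 without transgenic array 3, Jchain by -0.15 and 0.12 without these, and by 0.54 without control array 1, and Blnk by 0.088 without transgenic array 1 and 0.16 without control array 3.

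The remaining lists did not pass camera with the preset correlation. The adjusted p was 0.171 for mast cells, 0.210 for oxidative phosphorylation, 0.259 for endothelium and angiogenesis, 0.304 for antimicrobial and regenerating proteins, 0.330 for matrix proteases and for the interferon response, and 0.357 for endoplasmic reticulum stress. Several passed in other settings. Mast cells passed with no filter (median -0.56) and without transgenic array 3 (-1.77), the interferon response without transgenic array 3 (-0.57), antimicrobial proteins (-0.62) and endothelium (-0.36) without control array 2, matrix proteases (-0.52) and oxidative phosphorylation (0.13) without transgenic array 1, and oxidative phosphorylation with array quality weights (0.092). In each of these 7 lists 0 members passed over all genes and 0 when adjusted over the list alone. In total 14 of 25 lists passed, 9 higher and 5 lower, and 0 passed with the correlation estimated, where the lowest camera adjusted p was 0.493. Without control array 3 the count was 7. Groupings of the 6 arrays into 3 and 3 that mixed the genotypes gave 6 to 14 passing lists with the preset correlation. T and NK cells, tuft cells, enteric nerves and glia, adipose tissue, squamous epithelium, pancreatic acinar cells and small intestine and cecum had fewer than 5 measured genes and were not tested.

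**Figure D3:**
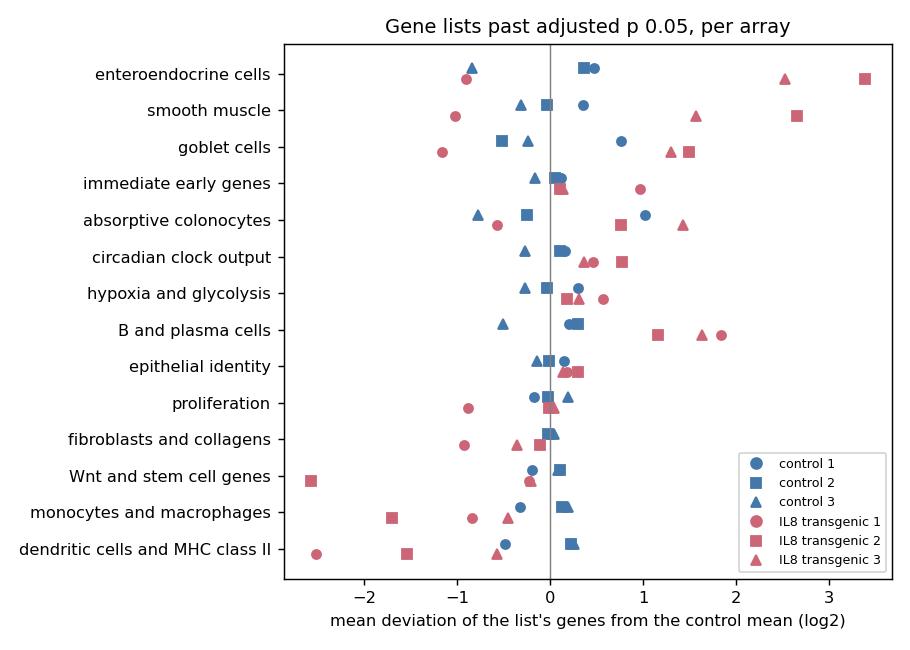
Mean deviation of each list's genes from the control mean (log2), 1 point per array, for the 14 lists with a camera adjusted p under 0.05, control in blue and IL8 transgenic in red. Transgenic array 1 lay at -2.52 for dendritic and MHC class II genes, transgenic array 2 at -2.57 for Wnt and stem cell genes and at 2.65 for smooth muscle.

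Genes of stratified squamous epithelium were higher on transgenic array 2 than on the other 5, and 4 of the 12 with a probe set passed the filter. On array 2 the keratin genes Krt14, Krt5 and Krt1 were at 12.93, 10.27 and 10.35 and Krtdap at 12.31, while the highest value on any other array was 8.04 for Krt14, 2.86 for Krt5, 2.11 for Krt1 and 2.62 for Krtdap. Trp63, the transcription factor of basal squamous cells, was at 8.97 on that array and at 2.29 or less elsewhere. Hoxb13, a gene of the distal colon, was at 11.96 to 12.13 on all 6 arrays. Hoxd13 was at 9.90 on control array 2, at 8.89, 11.62 and 10.44 on the transgenic arrays, and at 2.53 and 2.81 on control arrays 1 and 3.

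**Figure D4:**
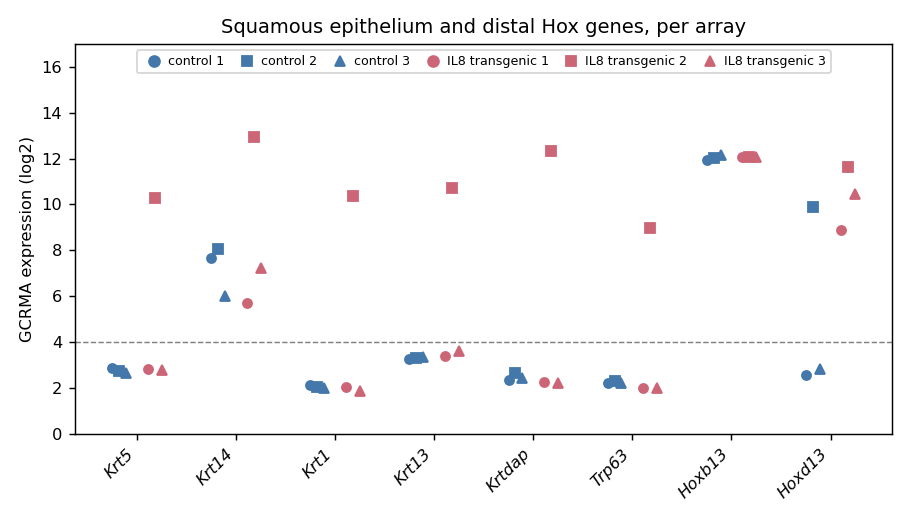
Expression (GCRMA, log2) of squamous epithelium genes and of Hoxb13 and Hoxd13, 1 point per array, control in blue and IL8 transgenic in red, with the level of 4 dashed. The squamous genes were highest on transgenic array 2, with Krtdap at 12.31, and Hoxd13 was under 4 on control arrays 1 and 3.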

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

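The 11 adjusted limma calls were 3 without the named X- and Y-linked genes, a setting chosen after seeing the data that removes 6 of the 11. They were 0 when probe sets under 4 on every array of a group were left out as well, a setting also chosen after seeing the data that selects on the outcome. It kept 18776 probe sets, and 971 had an unadjusted limma p under 0.05. All other settings gave 8 to 12, and an adjusted p threshold of 0.1 gave 11. Leaving out 1 array gave 8 to 11 calls. The 89 probe sets past the unadjusted threshold became 47 with the stricter filter, which tests fewer probe sets, and leaving out 1 array gave 47 to 421. The 14 lists became 0 with the correlation estimated and 7 to 15 with 1 array left out. Signal over background limits low genes, and only a bound can be given where a whole group lies under 4.

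With the replicate number as a block, 8 probe sets passed the adjusted threshold, all among the 11, 147 passed the unadjusted one, and 15 lists passed. The adjusted p of Ighm was then 0.424 and that of Uty 0.106. Deviations of arrays with the same number correlated at -0.267, -0.277 and -0.051, and 0 of 6 arrays correlated best with its own number, so the numbers do not pair the samples.

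Directions turned for lists and genes that had not passed, and for proliferation. The CXCR2 list ranked higher with no filter (median 0.14), with the block (0.17) and by ranks (0.17), and its median ran from -0.42 to 0.39 with 1 array left out. The camera direction also turned to higher, at medians still below 0, for the immature myeloid list with the block (-0.18), inflammatory cytokines with the stricter filter (-0.26), and the interferon response (-0.041) and endoplasmic reticulum stress (-0.013) with array weights. With 1 array left out, medians ran from -0.57 to 0.10 for inflammatory cytokines, -0.57 to 0.20 for interferon, -0.44 to 0.042 for proliferation, -0.52 to 0.18 for matrix proteases and -0.27 to 0.028 for endoplasmic reticulum stress. With array weights Ptgs2 was at 0.81 and Il1b at 0.044. With 1 array left out, Ptgs2 ran from -0.99 to 0.50, Il1b from -0.98 to 0.26, Cxcl2 from -0.42 to 0.60, Ppbp from -0.49 to 2.30 and Jchain from -0.15 to 0.54. The neutrophil list passed with no filter (adjusted p 0.0361) and with the block (0.0338), in a range of 0.0173 to 0.999 over all alternatives. The cause was not tested.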

Other observations

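In lists too small to test, single genes still set arrays apart. Pnliprp1, a lipase-related gene of the pancreatic list, was at 12.09 to 12.74 on the control arrays and at 10.47, 5.76 and 10.72 on transgenic arrays 1 to 3. The fatty acid binding gene Fabp2 was at 8.33 on control array 1 and at 8.26 and 7.44 on transgenic arrays 2 and 3, against 3.27 on transgenic array 1, and Apob was at 8.52 on control array 1, at 7.82 on transgenic array 3 and at 6.15 on transgenic array 2, where control array 2 had 6.72. Stmn2, a gene of nerve cells, was at 6.64 and 6.28 on transgenic arrays 1 and 2 and at 3.62 or less on the other arrays, while of other genes of the nerve and glia list Snap25 reached 4.19 on transgenic array 2, Ret lay at 6.37 to 8.77 on all 6 arrays, and Uchl1 and Prph stayed under 4. The T cell gene Cd3e was at 2.20 or less on every array, and the granzyme gene Gzma reached 5.72 on control array 2.

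Of the tests below, those of escape genes, the AFFX control probe sets, S100a8 and S100a9 without transgenic array 2, the glucocorticoid genes and the splits were fixed before their results were seen, and the others were chosen after. Xist was high and Y-linked genes were at background on all 3 transgenic arrays, which the labels call male. Loss of the Y chromosome in male tumours would leave Xist low, but its lowest value on a transgenic array was 12.26. As all 6 arrays are labelled male, an exchange of labels within the series would not account for the mismatch, and while 0 control arrays had high Xist, an exchange of both whole groups would also give 0 and stays open, since no probe set reads the transgene. Female mice under a wrong sex label are a candidate explanation, for which genes other than Xist that escape X inactivation had been predicted to lie above the 95th percentile of random draws of other X-linked genes, and their median difference of 0.11 missed it, at percentile 83.1, although all 5 measured were higher, as were Kdm6a (0.85) and Eif2s3x (0.45 at its brightest probe set, and 1.08 at the dimmer one that the rule for named genes took), left out because they had been seen. The upper bootstrap bound of that median, 0.63, was added after the miss was seen and lies above the 95th percentile of 0.20. With 5 genes such a bound is the highest member, here Kdm5c at 0.63, so it decides nothing. The prediction was thus missed. With only 5 genes, which differed by 0.02 to 0.63 with SE of 0.15 to 0.27, this miss cannot decide by itself whether the mice were female. Xist at 12.26 or more, with Eif2s3y, Kdm5d and Uty under 4 on all 3 transgenic arrays, argues against the male label of these samples. Genotype and sex cannot be told apart as sources of any other difference.

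Ighm was at least 2-fold above every control array on all 3 transgenic arrays at 1 of 7 kept probe sets. More B cells could raise Cd79a, Cd79b, Ms4a1, Cd22, Cr2, Pax5 and Fcrla, whose median difference was -0.062 with a range of -0.39 to 0.17, but 0 of these 7 passed the filter and the highest value on any array was 4.57, so genes this near background leave B cells open. More IgM plasma cells stay open too, since Jchain differed by 0.25, from 11.95 in control tumours, and by -0.15 without control array 3, and Mzb1 by 0.67, by 0.10 without control array 3 and by 0.20 without transgenic array 3. A sequence variant of Ighm between the mice could also separate 1 probe set. Of the other 6 kept Ighm probe sets, 0 had every transgenic array 2-fold above the highest control array. But 4 of the 6 had every transgenic array above every control array, by 0.28 to 0.86, which a variant read by 1 probe set alone would leave unexplained. These 4 read 1 gene and were all highest on transgenic array 1, so they are not independent observations. The 10% of probe sets that chance leaves without overlap, in either direction, therefore cannot be set against them. The rest of the 6 overlapped between the groups. These explanations cannot be told apart with these arrays, since the probes' sequences were not analysed here.

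Squamous genes were high on transgenic array 2, where 11 of 12 lay at least 4 above every other array on the log2 scale, which is consistent with squamous epithelium in that sample. For a fault of the whole array, the median deviation of its AFFX control probe sets, -0.0059, lay within the range of the other arrays, -0.061 to 0.059. The values as deposited have nearly equal medians on all arrays (3.31 to 3.36). A shift of a whole array may thus have been levelled out before deposit, so the AFFX probe sets leave such a fault undecided. Squamous epithelium also expresses S100a8 and S100a9, but without this array they still differed by 0.66 ± 0.24 (SE) and 0.79 ± 0.30, over 2 SE above 0, which argues against this sample as the whole source of the difference. Neither passed adjustment there (limma adjusted p 0.924 for both). No biological explanation of the squamous signal was tested.

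Fkbp5 and Sgk1 are induced by glucocorticoids, and a glucocorticoid response was a hypothesis for their higher values. A set of 11 measured genes of that response, without Per1 (1.11) and Dusp1 (0.74), which are higher but had been seen, did not rank higher in camera (p 0.379 with the preset and 0.640 with the estimated correlation, a median of 0.03), with 6 higher and 5 lower, from 1.15 for Tsc22d3 to -1.95 for Pdk4.

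Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 11 adjusted calls and the highest other 1, so that 1 split, the real one, reached 11. The real split is also the split by Xist. Of the 11 calls, 6 are probe sets of named X- and Y-linked genes, and 4 are unnamed and lay under 4 on every transgenic array. Any other split mixes arrays with and without Xist and so loses such calls, and the contrast does not speak for genotype. For the unadjusted count, 2 splits, the real one with 89 included, were as large, and the highest other gave 200. That split set control array 1 with transgenic arrays 2 and 3 against the rest, which points to a structure of the samples across genotype: these 3 arrays also had the highest colonocyte and goblet cell scores. For the lists, 2 splits gave 14, the real one included, and the other splits gave 6 to 14. Many lists thus passed with the preset correlation however the arrays were grouped, and the count of 14 does not speak for genotype.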
